A study of Mus musculus with 4 samples.

How the data were processed

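RNA from 4 cell populations of mouse small intestine was measured on cDNA arrays, with 1 sample per population. Per the labels' protocols, total RNA was reverse transcribed with mouse cytokine primers and a radioactive nucleotide, and the hybridised array images were quantified with Phoretix software. The authors subtracted the background and normalized each spot to negative controls and to beta-actin, per the labels. The deposited values are therefore normalized intensities on a linear scale, and the series' design text states that each stands for a duplicate measurement. The spread of the duplicates is not given in the sources used here, so no SD, SE or p-value is attached to any value.

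The deposited table has 532 rows, each named by an array position made of a letter, a number, and U or L. Neither the table nor the gene reference used here pairs these positions with genes, so no gene is named and positions are reported by their codes. The gene and cell type marker lists that had been fixed before the data were examined could not be applied, which left their medians and the scaling to housekeeping genes not run. Of the 532 rows, 6 had no value in any sample and were left out. Position C24U was exactly 100 in all 4 samples, so every value reads as a percent of that position. It was left out as the scaling position; the labels name beta-actin as the normalizing gene, but no source pairs that name with this position. The 4 corner positions held 1 repeated value within each sample and were left out as well, with 1 of them empty in the M cell sample. The remaining 521 positions were analysed, and 7 of them lie in the same array column, column 24, as the scaling position.

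Values in the M cell, VAE and PPL samples were all multiples of 0.005, with a tolerance of 1e-06 steps. In the UEA1-negative FAE sample 47.9% were multiples of 0.005 and all were multiples of 0.0025. The values of that sample were thus averaged over more readings, or in another way, than those of the other samples.

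From these intensities, ratios between samples were computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. The floor of a sample was the 25th percentile of its 521 values. Values under the floor were raised to it, and a position entered a comparison if it was above the floor in at least 1 of the 2 samples. A position was called higher or lower at a ratio of at least 2-fold. Where 1 side was under its floor, the ratio is a lower bound relative to that floor. These calls describe 4 arrays and carry no test of the populations. The comparisons were M cell against UEA1-negative FAE, VAE and PPL, and UEA1-negative FAE against VAE. The rule fixed before the data were examined would have named 10 positions in each direction per comparison, ranked by ratio among positions above the floor in both samples and at least 2-fold different, the 5 brightest in each direction whose other side lay under the floor, and the top 15 of those highest in M cells. Because positions could not be tied to genes, the first 2 by ratio in each direction are named here, and any other named position was chosen after its values were seen.

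The ratio step was tested on simulated data for M cell against VAE, built from the 521 VAE values with noise of 0.2 (SD, log2). Of 50 positions raised by 4-fold, 100% were called. That outcome was nearly fixed, because the rise was well over the 2-fold threshold and the noise was low. Of 50 positions lowered by 4-fold, 34% were called; most VAE values lie within 2-fold of the floor, with a 75th percentile of 4.39 and a floor of 2.24. Falls from a dim level are therefore mostly invisible at this depth of signal. None of the unchanged positions was called in that simulation (0%), an outcome nearly fixed by the low noise chosen. The spread between M cells and VAE gave a larger assumed error, 0.36 (SD, log2) per array. The 0% is thus no estimate of false calls on the deposited arrays, and the 100% is no estimate of the rises found there.

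Alternatives fixed in advance were median scaling, quantile normalization, no floor, floors at the 10th and 50th percentiles, a pseudocount equal to the 25th percentile in place of the floor, and thresholds of 1.5-fold and 3-fold. Chosen after seeing the data were scaling to the corner positions, alignment of the 10th percentiles by subtraction, leaving out column 24, and leaving out the UEA1-negative FAE sample. Correlations were computed across positions, which are not independent replicates. No paired analysis was possible because each population had 1 sample.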

Results

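The study profiled M cells, the antigen-sampling cells of the epithelium over intestinal lymphoid follicles, beside 3 related mouse populations. The follicle-associated epithelium (FAE) was released from Peyer's patches, the lymphoid follicles of the small intestine, and was split with UEA1, a fucose-binding lectin. The cells that bound UEA1 formed the M cell sample and the cells that did not formed the UEA1-negative FAE sample. Villus-associated epithelium (VAE) came from intestine without Peyer's patches and was depleted of cells carrying the leukocyte antigen CD45. Peyer's patch lymphocytes (PPL) were selected for CD45. The FAE digest contained lymphocytes, per the protocol, and no CD45 depletion is described for either FAE fraction. Each population was represented by 1 sample, so the differences below have no replicate check. No position is tied to a gene in the sources used here, so results are given for array positions.

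The 521 analysed positions were mostly dim in all 4 samples. The median intensity, in percent of the scaling position, was 3.16 in M cells, 5.26 in UEA1-negative FAE, 2.92 in VAE and 4.85 in PPL. The lower limit used for ratios, the 25th percentile, was 2.52, 4.30, 2.24 and 4.06 in the same order. Positions at an intensity of 20 or more numbered 17 in M cells, 9 in UEA1-negative FAE, 19 in VAE and 26 in PPL. The 90th percentile was 4.25 times the 10th in M cells, 4.79 times in VAE and 4.01 times in PPL, against 2.50 times in UEA1-negative FAE. Of the 7 positions of column 24, all 7 were above the 90th percentile in M cells and 5 in each of the other samples, with medians of 55.9 in M cells, 45.0 in UEA1-negative FAE, 29.7 in VAE and 73.2 in PPL.

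**Figure D1:**
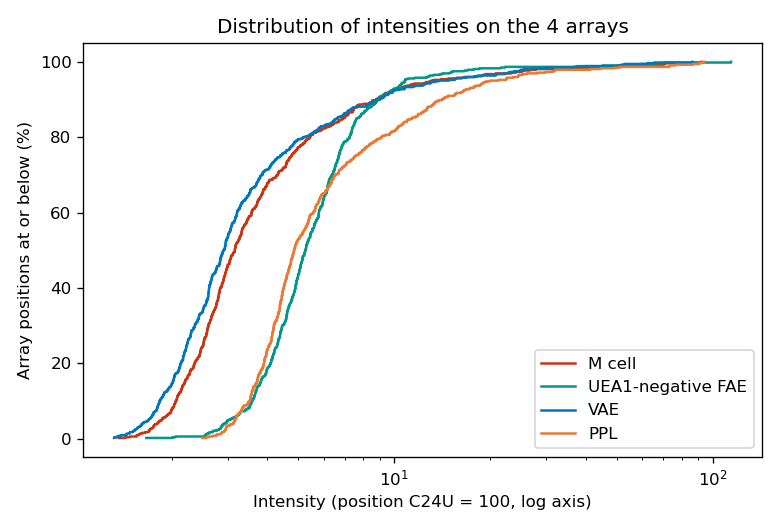
Cumulative share of the 521 array positions (vertical axis, percent) at or below each intensity (horizontal log axis, position C24U set to 100), with 1 line per sample. The low end of UEA1-negative FAE and PPL lies to the right of M cells and VAE, with medians of 5.26 and 4.85 against 3.16 and 2.92.

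Across positions, the M cell array was closest to VAE. The rank correlation (Spearman) of M cells was 0.69 with VAE, 0.66 with PPL and 0.43 with UEA1-negative FAE, the other part of the same tissue preparation. UEA1-negative FAE correlated at 0.32 with VAE and 0.42 with PPL, and VAE correlated at 0.54 with PPL. Without column 24 the values for M cells were 0.68, 0.65 and 0.41. The order differed among the 47 positions outside column 24 with a mean of at least 10 over M cells, VAE and PPL. There M cells correlated at 0.72 with VAE, 0.51 with UEA1-negative FAE and 0.08 with PPL, and VAE correlated at -0.34 with PPL. Picking positions by the mean of M cells, VAE and PPL can itself lower the correlations among these samples. Among the 468 dimmer positions the values for M cells were 0.60 with VAE, 0.56 with PPL and 0.30 with UEA1-negative FAE. Positions are not independent replicates, and the order of these correlations has no replicate error.

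The first comparison asked how UEA1-binding cells differ from the remainder of the FAE. Of 464 positions compared, 16 were at least 2-fold higher in M cells, 114 were at least 2-fold lower and 334 were within 2-fold. In 14 of the 16 higher positions UEA1-negative FAE had the lowest value of the 4 samples. The VAE value was above that of UEA1-negative FAE in 15 of the 16, in 11 by at least 2-fold, and the PPL value was likewise above it in 15, in 11 by at least 2-fold. The 16 were picked for a low value on the UEA1-negative FAE array against M cells, so that array's own error favours these counts. Among positions above the floor in both samples, as for the named positions throughout, the largest difference was at F16U, with 70.8 in M cells and 13.3 in UEA1-negative FAE (5.32-fold), and F16U also read 50.2 in VAE and 32.0 in PPL. Position C16L followed with 49.8 against 9.36 (5.32-fold), and read 39.5 in VAE and 22.5 in PPL. The largest differences the other way among such positions were dimmer, at O2L with 2.61 in M cells against 10.4 (3.98-fold lower) and at L20L with 2.80 against 10.6 (3.78-fold lower). In 47 of the 114 lower positions the M cell value was under its floor, so their ratios are lower bounds. Higher calls were confined by the rule to M cell values at least 2-fold above the UEA1-negative FAE floor of 4.30. The 90th percentile of M cells was 8.77, so few positions could be called higher. The median ratio of all positions was 0.64 (log2 -0.64), so the split of calls depends on the scaling. After each array was scaled to its median over the positions above the floor in all 4 samples, 32 positions were higher and 37 lower. The share of higher calls was then 46.4% against 12.3% as deposited, and F16U was 7.01-fold higher while O2L was 3.02-fold lower.

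**Figure D2:**
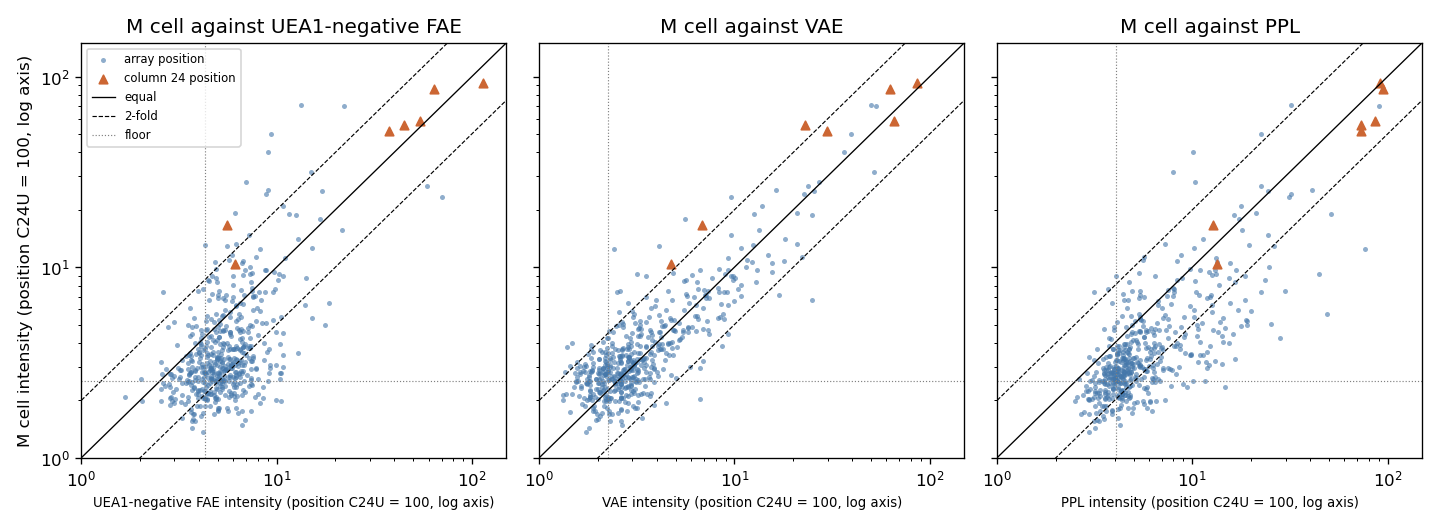
Intensity of each array position in M cells (vertical log axis) against UEA1-negative FAE, VAE and PPL (horizontal log axes), position C24U set to 100; triangles mark column 24, solid and dashed lines mark equality and 2-fold, and dotted lines mark the floors. In the VAE panel 439 of 460 compared positions were within 2-fold, against 334 of 464 for UEA1-negative FAE and 346 of 455 for PPL.

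M cells were next compared with villus epithelium. This was the most similar pair by count of calls, with 14 positions at least 2-fold higher in M cells, 7 at least 2-fold lower and 439 of 460 (95.4%) within 2-fold. The higher positions were mostly high in lymphocytes: 11 of the 14 were also at least 2-fold higher in PPL than in VAE, where independent lists would share 4.07, and both ratios use the same VAE array. After median scaling, 6 of the 14 were at least 2-fold higher in PPL than in VAE. In 9 of the 14 the PPL value was above the M cell value. Position M7U was highest by ratio, at 12.5 in M cells and 2.41 in VAE (5.18-fold), and read 76.6 in PPL and 8.25 in UEA1-negative FAE. Position E19L read 17.8 in M cells and 5.60 in VAE (3.19-fold), close to its 17.3 in PPL and 16.6 in UEA1-negative FAE. Column 24 supplied 3 of the 14. All 7 lower positions were also lower in PPL than in VAE, and both ratios again use the same VAE array. Among them, H9L read 6.77 in M cells and 24.9 in VAE (3.68-fold lower), and J3U read 7.15 and 16.9 (2.36-fold lower). The median ratio was 1.07 (log2 0.10), and median scaling gave 13 higher and 10 lower positions.

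M cells were also compared with Peyer's patch lymphocytes. Of 455 positions, 7 were at least 2-fold higher in M cells, 102 were at least 2-fold lower and 346 were within 2-fold. A higher call needed an M cell value at least 2-fold above the PPL floor of 4.06. All 7 higher positions were also higher in VAE than in PPL, and both ratios use the same PPL array. Position B2U read 40.3 in M cells, 36.6 in VAE and 10.0 in PPL, a ratio of M cells over PPL of 4.02-fold. Position L6L read 31.8 in M cells, 51.6 in VAE and 7.93 in PPL, a ratio of 4.01-fold. Among the lower positions, J7U read 5.70 in M cells and 49.1 in PPL (8.62-fold lower), and M7L read 4.26 and 28.2 (6.63-fold lower). The median ratio was 0.63 (log2 -0.66). Median scaling gave 20 higher and 36 lower positions, which moved the share of higher calls from 6.42% to 35.7%. All 36 of those lower positions were among the 102, which is certain when a single factor raises every ratio of M cells over PPL.

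No position was at least 2-fold higher in M cells than in each of the other 3 samples. The rule could only be met by M cell values at least 2-fold above the UEA1-negative FAE floor of 4.30, so dimmer positions could not qualify. The nearest was G6L, singled out after its values were seen, which read 7.45 in M cells, 2.61 in UEA1-negative FAE, 2.51 in VAE and 3.13 in PPL. Its readings in UEA1-negative FAE and PPL were under the floors of those samples, and against those floors the smallest ratio was at least 1.73-fold. With no floor its smallest ratio was 2.38-fold, and after median scaling it was 2.28-fold, so this position passed 2-fold under both. Position F16L, with 7.46 in M cells, had a smallest ratio of 2.03-fold after median scaling and of 1.39-fold with no floor. By the same rule 10 positions were highest in UEA1-negative FAE, 2 in VAE and 46 in PPL, or 11, 6 and 21 after median scaling.

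The last comparison set the UEA1-negative FAE against villus epithelium. Of 485 positions, 173 were at least 2-fold higher in UEA1-negative FAE, 22 were at least 2-fold lower and 290 were within 2-fold. Position G22L stood out at 69.9 in UEA1-negative FAE and 9.55 in VAE (7.32-fold), and read 23.4 in M cells and 31.4 in PPL. The next position above both floors, O5U, read 10.5 against 2.44 (4.32-fold), with 1.99 in M cells. The lower positions were led by H9L at 5.47 against 24.9 (4.56-fold lower) and C16L at 9.36 against 39.5 (4.22-fold lower). Lower calls were confined by the rule to positions bright in villus epithelium. UEA1-negative FAE values were raised to its floor of 4.30, and VAE had to be at least 2-fold above that. In 85 of the 173 higher positions VAE was under its floor. The median ratio was 1.70 (log2 0.76), and median scaling gave 49 higher and 46 lower positions, a share of higher calls of 51.6% against 88.7%.

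Positions that set both FAE fractions apart from villus epithelium were few. As deposited, 7 positions were at least 2-fold higher than VAE in both M cells and UEA1-negative FAE, and included M7U, E19L and G22L. All 7 also read higher in PPL than in VAE, from 3.87 against 2.85 at M19U to 76.6 against 2.41 at M7U. As deposited, PPL read higher in general, with medians over all positions of 4.85 in PPL and 2.92 in VAE. The M19U value was under the PPL floor of 4.06. That all 7 read higher in PPL is therefore no link to lymphocytes by itself. Over the 447 positions compared in both, 14 were higher in M cells and 141 in UEA1-negative FAE, and independent lists of these sizes would share 4.42. Simulated arrays with no change against the VAE array, with an assumed error of 0.36 (SD, log2) taken from the spread between M cells and VAE, shared 1.94 on average and 9 at most in 1000 draws. These arrays lacked the median shift of 1.70-fold of UEA1-negative FAE over VAE. They are therefore no like baseline for the shared counts as deposited, higher or lower. Both H9L and J3U, named after their values were seen as a pair, were at least 2-fold lower than VAE in both fractions, where independent lists would share 0.34 and the same simulated arrays shared 0.61 on average and 4 at most. H9L and J3U also read lower in PPL than in VAE, at 4.69 and 5.42 in PPL. Part of any excess can come from the shared VAE array, which cannot be split. Median scaling gave 3 shared higher and 6 shared lower positions.

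**Figure D3:**
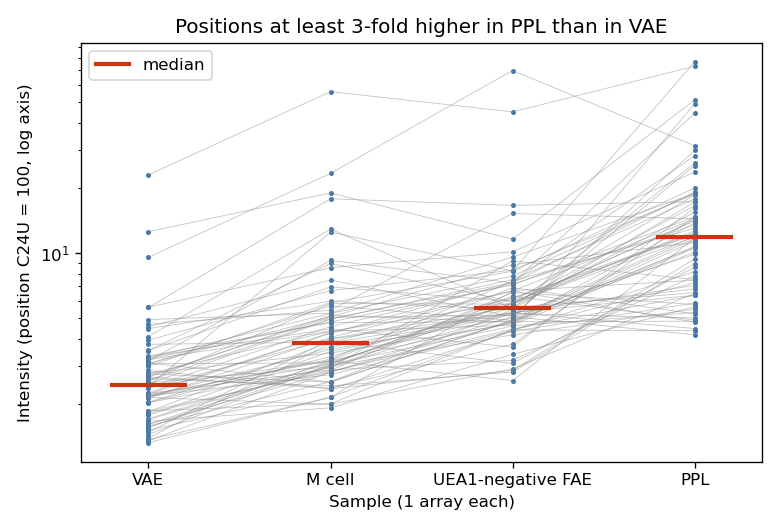
Intensity (log axis, position C24U set to 100) of the 74 positions at least 3-fold higher in PPL than in VAE, with 1 grey line per position across the 4 samples and red bars at the medians. The medians were 2.45 in VAE, 3.85 in M cells, 5.57 in UEA1-negative FAE and 11.9 in PPL, so the medians of both FAE fractions lay between the other 2 as deposited. Picking positions for a gap between PPL and VAE makes an in-between value likely. Over all 521 positions the medians were 3.16 in M cells and 5.26 in UEA1-negative FAE.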

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

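The 4 corner positions, which no comparison used, carried strong signal in every sample: 99.5 in M cells, 128.1 in UEA1-negative FAE, 102.3 in VAE and 101.9 in PPL, in percent of the scaling position. What is spotted there is not given in the sources used here.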

How the results depend on the processing

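Of 122 recomputed counts, 59 stayed within 1.5 times the value as deposited and 63 did not. In this paragraph pairs give higher then lower positions, and the cause of each change was not tested except that thresholds and floors act by construction. Median scaling gave 32 and 37 for M cells against UEA1-negative FAE, 20 and 36 against PPL, 49 and 46 for UEA1-negative FAE against VAE, 2 highest in M cells, and 3 and 6 shared over VAE. Quantile normalization gave 37 and 41, 21 and 25, 46 and 43, 2, and 4 and 4. Aligned low ends (chosen after seeing the data) gave 39 and 48, 20 and 61, 63 and 44, 1, and 3 and 6. Corner scaling (likewise) gave 31 and 42 against UEA1-negative FAE and 81 higher for UEA1-negative FAE against VAE. M cells against VAE stayed within 1.5 times of 14 and 7 under these 4 scalings. The pseudocount gave 8 higher against UEA1-negative FAE, 9 and 1 against VAE, 4 higher against PPL, 11 lower for UEA1-negative FAE against VAE, and 4 and 1 shared. No floor gave 13 shared higher and 1 highest in M cells, the 10th percentile floor also 1, and the 50th percentile floor 70 lower against UEA1-negative FAE and 108 higher for UEA1-negative FAE against VAE. At 1.5-fold the counts were 34 and 260 against UEA1-negative FAE, 61 and 28 against VAE, 17 and 256 against PPL, 308 and 38 for UEA1-negative FAE against VAE, 1 highest in M cells, and 46 and 15 shared. At 3-fold they were 7 and 20, 3 and 1, 2 and 35, 35 and 9, and 1 and 1 shared. Leaving out the UEA1-negative FAE sample left 0 highest in M cells. The list medians and housekeeping scaling were not run, since positions have no gene names. No paired analysis was possible because each population had 1 sample. Most signals lay within a few-fold of the floor, which limits the falls that can be seen.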

Other observations

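Lymphocytes and villus epithelium, which the report did not set against each other directly, gave 140 positions at least 2-fold higher in PPL and 11 lower among 462 compared, or 52 and 36 after median scaling. At the 11 positions at least 2-fold higher in VAE than in PPL, the M cell value was closer to VAE than to PPL in 8, with a median of 0.64 times VAE. The UEA1-negative FAE value was closer to VAE in 0 of the 11, with a median of 0.30 times VAE. These positions were picked with the VAE array, so its own error adds to both distances from it.

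In the tests below, the uniform background on the M cell array and the position effect were set out before their values were seen; the lymphocyte RNA test, the uniform offset tests, the dim-signal noise of the UEA1-negative FAE array and the bleed tests in their present form were chosen after.

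The M cell array lay between VAE and PPL at 67 of the 74 positions at least 3-fold higher in PPL than in VAE, though picking positions for such a gap makes an in-between value likely. The median excess of M cells over VAE was 1.45 at these positions. It was 0.12 at the 339 positions where PPL and VAE were within 1.5-fold after median scaling, a ratio of 12.1. Picking positions with the VAE array can itself raise the 1.45. Arrays simulated with error alone gave an excess of at most 0.45 (mean -0.0037), but left this picking out, so they cannot size its part. In a further check, 44 positions were picked by PPL alone, and M cells were above VAE in 37. The median ratio of M cells over VAE was 1.50 there, against 1.04 at the 339 positions. These values argue against a higher uniform background on the M cell array. A candidate explanation is lymphocyte RNA in the UEA1-binding fraction, since no CD45 depletion is described for it. The implied share of PPL signal in M cells had a median of 16.1% (quartiles 8.90% and 29.9%), or 13.7% with low ends aligned and 19.0% over 26 positions after median scaling. The same share had a median of 31.5% in UEA1-negative FAE as deposited, so an in-between value was not particular to M cells. A raised low end of an array also raises this share. For M cells as deposited, 54.1% of positions lay within 2-fold of the median, between the bounds set for and against a single source. The spread that array error alone would give to shares from a single source was not simulated. The spread of the shares therefore cannot decide for or against lymphocyte RNA. Expression of the same genes by M cells themselves stays open and untested.

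The UEA1-negative FAE array stood apart in its narrow range and, over all and over dim positions, in its low rank correlations. Over bright positions its correlations were not the lowest, but these positions were picked by their mean over M cells, VAE and PPL. Such picking can lower the correlations among those arrays, so the bright positions cannot decide whether the UEA1-negative FAE array stands apart there. A uniform offset or scaling is argued against for the low correlations over all positions, because it keeps their order, yet the highest with another array was 0.43, below the lowest of 0.54 among the other 3; it stays open for the narrow range, since with low ends aligned the 90th over the 10th percentile was 3.93 in UEA1-negative FAE and 4.64 or more on the other arrays. Position-dependent background could be part of the low correlation with M cells, since removing row and column medians raised it by 0.059, to 0.49. The same step moved the correlations of UEA1-negative FAE less with VAE, from 0.324 to 0.335, and with PPL, from 0.419 to 0.435. It lowered those among the other 3 arrays, to 0.674 for M cells with VAE, 0.633 for M cells with PPL and 0.499 for VAE with PPL. The highest correlation of UEA1-negative FAE, 0.487, was then only just below the lowest among the other 3, 0.499. Noise in dim signal may be part for dim positions, where the highest correlation was 0.30 against a lowest of 0.44 among the other 3 arrays, but was not shown to account for bright positions, where the correlation with M cells was 0.51, against 0.72 for M cells with VAE and 0.08 for M cells with PPL. A real difference of the UEA1-negative cells cannot be told apart from position effects and dim-signal noise with 1 array.

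Positions high in PPL shared array addresses. Of 250 addresses with both a U and an L position, 17 had both at least 3-fold higher in PPL than in VAE, against a mean of 5.02 and a maximum of 13 over 10000 shuffles. Bleed of a bright spot into its neighbour could give such pairs and stays open: the 17 spots of at least 20 in PPL with a partner under 20 had partners at a median of 1.39 times the array median (95% bootstrap interval 0.96 to 2.61), which leaves out M7U and M7L, 1 of the 5 pairs with a spot of at least 20, because both exceed it. In the other 12 the dimmer spot had a median of 0.82 times the signal of the brighter. The median was 0.27 over all 18 addresses with a spot of at least 20 in PPL, whether or not both spots were high in PPL over VAE. After the array median was subtracted from both, the median ratio was 0.53 in the 12 pairs and 0.11 at the bright addresses. The ratios still overlapped, with a 25th percentile of 0.18 in the 12 pairs and a 75th percentile of 0.31 at the bright addresses. The 12 pairs were picked with both spots at least 3-fold over VAE and under 20, the bright addresses by 1 spot alone. That picking can itself raise the ratio in the 12 pairs, so the contrast cannot decide on bleed. Placement of related genes side by side was not tested, because positions have no gene names.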
